A study of Homo sapiens with 6 samples.

How the data were processed

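DLD1 is an established human colorectal cancer cell line. Per the labels' protocols, RNA-seq was done on DLD1 cells co-cultured with fibroblasts called S-CAFs and on DLD1 cells co-cultured with CAFs, and m7G MeRIP-seq, in which RNA fragments carrying 7-methylguanosine are pulled down with an antibody and sequenced beside the unselected input, was done on DLD1 cells after METTL1 knockdown and on control cells. The series title speaks of senescent CAFs and of SASP cytokines, the factors that senescent cells secrete. There were 6 libraries, with 1 library in each group: S-CAFs-w13, DLD1-W13CM, knockdown input, knockdown m7G immunoprecipitate (IP), control input and control m7G IP. The title S-CAFs-w13 names its co-culture. DLD1-W13CM was taken as the CAF co-culture because it is the other RNA-seq library. Its title does not say so and does not explain the letters CM, so a culture of another kind is not excluded. These RNA-seq libraries are named by their titles throughout. The knockdown libraries are titled sh2-Input and sh2-IP, and the control libraries sh-NT-Input and sh-NT-IP. The knockdown thus rests on a single construct, sh2. The series design mentions replications of the knockdown and control cells, but the labels hold a single input and a single IP library of each.

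Total RNA was isolated with TRIzol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name cutadapt 2.5, HISAT2 2.1.0, featureCounts 1.6.3, DESeq2 with no version, SAMtools 1.10 and HOMER 4.10.4, and the builds GRCh38, hg38 and GRCm38, without saying which step used which. The caller of the m7G peaks and of their change is not given in the sources used here. The expression values deposited by the authors are FPKM, fragments scaled to gene length and library size; the FPKM unit of the knockdown table's input columns was inferred from values that behave as those of the co-culture table. The co-culture table held 21519 genes, and the knockdown table held 9450 genes, each with 1 listed m7G peak, so genes without a peak were not analysed in the knockdown comparison. The authors also deposited a log2 fold change with a p-value and an adjusted p-value per gene for each expression comparison, per the file headers. For each peak they deposited a fold enrichment (a ratio of IP to input; over which libraries is not stated), a log2 change in m7G between the lines, and the log10 of its p-value and FDR, per the file headers. Which line is the numerator of the m7G change is not stated; it was taken as knockdown over control, as for the input log2 fold change, whose direction was checked on the input FPKM. A depth of the IP libraries and IP values per line were not analysed here.

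The ratio of the FPKM columns of a table was a ratio of whole numbers times a constant, to a relative tolerance of 1e-14, for 20805 of 20806 genes above 0 in both co-culture libraries, the exception being MT-RNR2, and for all 9348 in the knockdown table; of the same ratios moved at random, 9 and 0 passed. This tolerance was set after the data were seen. From these steps and RefSeq lengths of mitochondrial genes and small RNAs, the effective library sizes, the largest that left gene lengths whole, came out at 6337930 for DLD1-W13CM, 6215550 for S-CAFs-w13, 10454200 for control input and 11625200 for knockdown input. Of the RefSeq lengths used, 78.8% were matched in the co-culture table, and of the lengths recovered there and used for the knockdown table, 85.0%. For each gene with a whole length the smallest whole read numbers that the values allow were used to give an exact (Clopper-Pearson) 95% counting interval of the fold; true read numbers can be whole multiples of these, so the intervals are at their widest. They cover counting error only, since PCR copies are not independent molecules. Genes listed at 0 in a library, 359 in DLD1-W13CM and 354 in S-CAFs-w13, have no recovered reads and no fold. Of the genes above 0 in both libraries, 59 in the co-culture table, MT-RNR2 among them, and 53 in the knockdown table had no recovered reads, since no multiple up to 60 gave a whole length, and have a fold without an interval.

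Expression was compared as log2((FPKM + 1)/(FPKM + 1)), which understates the change of low genes, while folds in the text are plain FPKM ratios, over genes with a mean of at least 1 FPKM. With a single library per group there is no replicate check, no test across libraries and no p-value of the comparison; a gene past 2-fold describes these libraries, not the conditions. The 26 gene lists, the measures, the 1 FPKM filter, the pseudocount, the 2-fold count and the naming rule were fixed before the data were examined. Set after the data were seen were the percentile limits of a list call, the minimum of 3 members, the m7G threshold, and the 250 nt that define a peak near a 5' end. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 10 bins, and called beyond the random lists when its percentile lay under 2.5 or over 97.5; this was done for lists with at least 3 measured members. List genes were found by Ensembl gene ID through a table of current symbols, and otherwise by the symbol in the table. The named genes are METTL1 and WDR4; the 10 highest and 10 lowest named protein-coding genes by log2 ratio; from each list the up to 4 members with the largest absolute log2 ratio and any with an absolute log2 ratio of at least 1; and for m7G the 10 largest gains and 10 largest losses past an FDR of 0.05, the level taken as threshold since the table states none. EPCAM, VIM, COL1A1, PDGFRB, COL6A1, ZC3H12A, the mitochondrial rRNAs and the single genes that open the other observations were named outside this rule, after their values were seen. Some genes that the rule names are not reported here. Peak coordinates are those of the authors' table, counted from 1. Of the 8515 peaks whose gene symbol is in RefSeq GRCh38.p14, 98.7% overlapped that gene.

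The calculations were tested on simulated reads drawn at the recovered depth. For the co-culture comparison, 168 of 200 genes changed 4-fold were found past 2-fold among 20747 genes, and 345 unchanged genes passed by counting noise. For the knockdown input comparison, 184 of 200 such genes were found among 9295 genes, and 7 unchanged genes passed. Of 200 random lists of 20 genes, 10 were called in the co-culture simulation and 13 in the knockdown simulation. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median centring, rescaling without the 1% highest genes, protein-coding genes only, stricter m7G thresholds, an IP over input ratio recomputed per line and 1.5-fold overlaps. Counting intervals were planned for raw counts, and the tables gave FPKM. Added after the data were seen were the authors' scaling, leaving out the mitochondrial genome, the counting interval of the recovered reads, the overlap of the expression comparisons, the reading of the m7G change as control over knockdown, and a 95% interval of a difference of medians from 10000 resamplings of peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.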

Results

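Gene expression was measured in DLD1 colorectal cancer cells co-cultured with S-CAFs (library S-CAFs-w13) or, by elimination, with CAFs (library DLD1-W13CM), and input RNA and m7G immunoprecipitates were measured in DLD1 cells with METTL1 knockdown and in control cells. METTL1 is the methyltransferase that, with its partner WDR4, writes internal m7G in tRNA and other RNAs. The effective library sizes recovered from the deposited FPKM values were 6337930 (DLD1-W13CM), 6215550 (S-CAFs-w13), 10454200 (control input) and 11625200 (knockdown input). Each group held 1 library, so no difference below has a replicate check; intervals in parentheses are 95% counting intervals of the FPKM ratio. Genes past 2-fold were counted on the log2(FPKM + 1) scale, where low genes need a larger FPKM ratio to pass.

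The co-culture comparison asks how DLD1 cells differ beside S-CAFs and beside CAFs, provided that DLD1-W13CM is the CAF co-culture. Its title does not say so. If the libraries also differ in how the cells were cultured, that cannot be told apart from the kind of fibroblast. In S-CAFs-w13, the cholesterol synthesis list was higher, and the proliferation list, the NF-kB target list and the mRNAs of the mitochondrial genome were lower, each beyond random lists. INSIG1, a sterol-regulated brake on cholesterol synthesis, stood at 6.83 FPKM in DLD1-W13CM and 137 FPKM in S-CAFs-w13, 20-fold higher (17.0 to 23.6). HSPA5, the main chaperone of the endoplasmic reticulum, was 10.5-fold higher (10.2 to 10.9), at 165 and 1733 FPKM. CXCL1 was 38.7-fold lower (18.5 to 97.1), at 33.6 and 0.869 FPKM. The proliferation marker MKI67 was 2.43-fold lower (2.33 to 2.54), at 88.1 and 36.3 FPKM.

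METTL1 was 2.71-fold lower in S-CAFs-w13 (1.75 to 4.29), at 4.82 FPKM in DLD1-W13CM and 1.78 FPKM in S-CAFs-w13, from at least 80 and 29 reads. The authors' deposited table gave METTL1 a log2 fold change of -1.58 there. WDR4 stood at 4.32 and 3.17 FPKM, and the interval of its fold in FPKM, 0.947 to 1.97 lower, included no difference. The authors' deposited log2 fold change of WDR4 was -0.59, on their own scaling. Other members of the list of m7G methyltransferases and cap genes went both ways: RNMT, which methylates the mRNA cap, was 2.45-fold higher and the decapping enzyme DCP2 2.42-fold higher, while the cap-binding NCBP1 was 2.08-fold lower. The list's median log2 ratio of -0.12 lay at percentile 23.3 of the random lists.

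Of 14739 genes with a mean of at least 1 FPKM, 1338 were at least 2-fold higher and 1167 at least 2-fold lower in S-CAFs-w13, so that 53.4% of these genes were higher. The median log2 ratio of all genes was 0.02. The authors' log2 fold changes equal the log2 FPKM ratios shifted by -0.14. With that shift added to the log2(FPKM + 1) ratios, called the authors' scaling here, 988 genes were at least 2-fold higher and 1545 lower, 39.0% higher. These are not counts of the authors' own log2 fold changes, which have no added 1 FPKM. Without the genes of the mitochondrial genome, with both libraries rescaled, 921 were higher and 1614 lower, 36.3% higher, with the median of all genes shifted by -0.17. Of the 2-fold genes, 201 were listed at 0 in a library, and these and 2 others have no counting interval. The 95% counting interval excluded 2-fold for 653 higher and 500 lower genes. Of the genes named below, ASNS, CHAC1, EREG, LAMB3 and MMP14 were no longer 2-fold higher on the authors' scaling of the log2(FPKM + 1) ratios. The authors' own log2 fold changes were 1.55 for ASNS and 1.45 for MMP14, past 2-fold. They were 0.953 for CHAC1, 0.891 for EREG and 0.924 for LAMB3.

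The 10 highest protein-coding genes included INSIG1, PADI1, DUSP5, HSPA5, CDKN1C, DDIT4, HERPUD1, CHI3L1 and MSMO1. PADI1 was 31.6-fold higher (21.3 to 49.2). The cell cycle inhibitor CDKN1C stood at 0.549 and 14.7 FPKM, 26.7-fold higher (13.8 to 59.2). DUSP5, a phosphatase of ERK, stood at 47.8 and 590 FPKM. The 10 lowest were CXCL1, CXCL2, CCL20, FAM111B, HIST1H4B, PI3, MT-CYB, HIST1H2AK, NCOA5 and CST1. FAM111B was 15.1-fold lower, PI3 14.7-fold lower and NCOA5 15.7-fold lower. HIST1H4B, HIST1H2AK and CST1 stood at 7.92, 5.62 and 5.25 FPKM in DLD1-W13CM and were listed at 0 in S-CAFs-w13; histone genes are near-identical copies whose reads can be split or lost in counting.

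**Figure D1:**
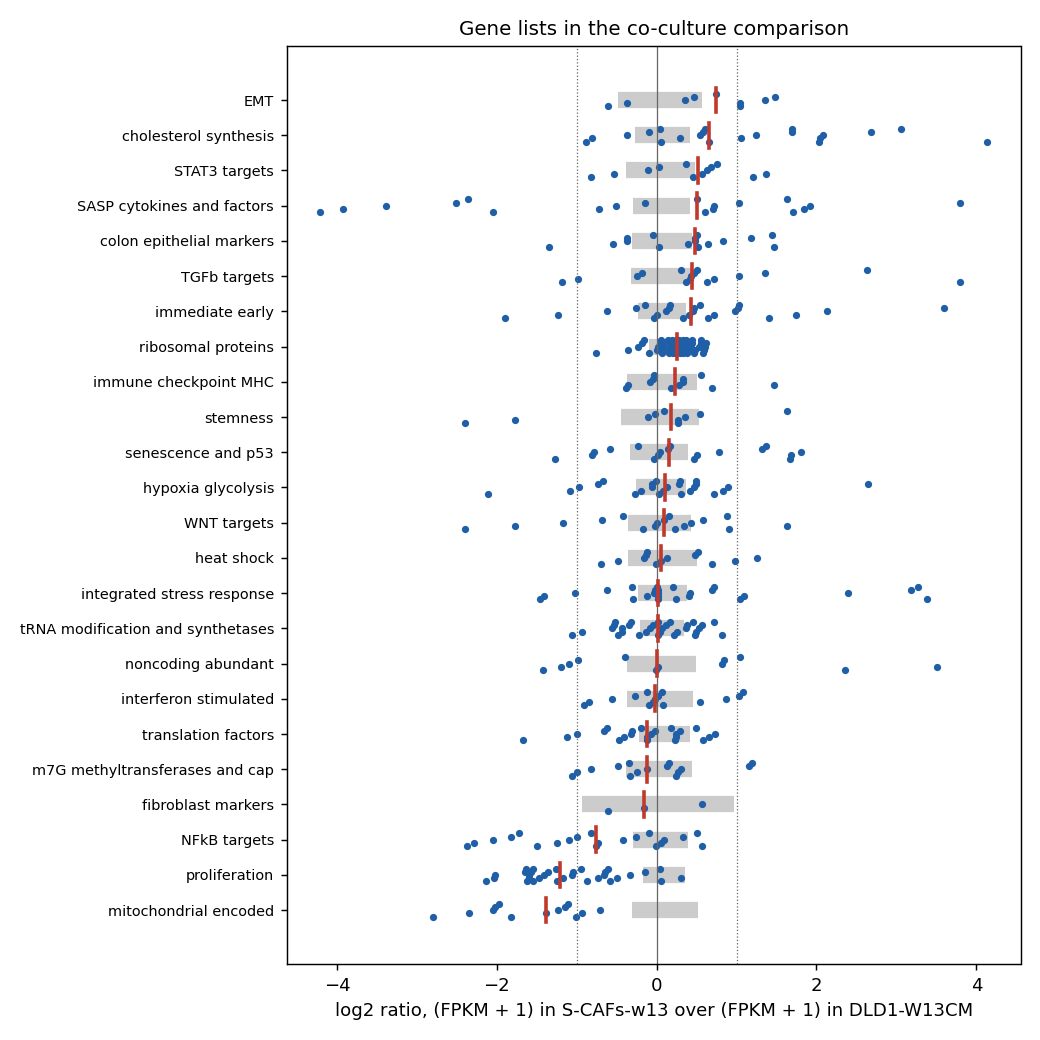
Log2 ratio of (FPKM + 1) in S-CAFs-w13 over DLD1-W13CM (x axis) for the measured members of each gene list with at least 3 measured members (rows, ordered by median). Points are genes, red bars are list medians, grey bars span the central 95% of the medians of 10000 matched random lists, and dotted lines mark 2-fold; the lowest medians are those of the mitochondrial (-1.39), proliferation (-1.21) and NF-kB (-0.76) lists.

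Of 24 lists with enough measured members, 10 lay beyond the random lists, 7 above and 3 below, where 1.2 would by chance for lists of independent genes. The proliferation list had 19 of 32 members at least 2-fold lower and 0 higher, a median of -1.21 below all random lists (percentile 0); its lower members included RRM2 (4.74-fold lower), TYMS (4.3-fold), the transcription factor E2F1 (5.39-fold) and the replication factor MCM2 (3.23-fold). All 13 mRNAs of the mitochondrial genome were below 0, 11 of them at least 2-fold lower, with a median of -1.39 (percentile 0); MT-CYB was 6.97-fold lower (6.78 to 7.17), MT-ATP6 4.14-fold lower and MT-CO1 2.62-fold lower. The mitochondrial rRNAs, outside the naming rule and chosen after their values were seen, stood at 46047 and 46108 FPKM (MT-RNR1) and at 55039 and 56893 FPKM (MT-RNR2), and the nuclear noncoding RNAs MALAT1 and NEAT1 were 5.13-fold and 11.9-fold higher. Of the NF-kB list, 8 of 21 members were at least 2-fold lower and 0 higher (median -0.76, percentile 0.01), among them NFKBIZ (6.3-fold lower), the complement factor C3 (7.51-fold), NFKBIA (3.84-fold) and the adhesion molecule ICAM1 (3.47-fold).

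In the cholesterol synthesis list, 10 of 21 members were at least 2-fold higher and 0 lower (median 0.65, percentile 99.97). HMGCS1 was 6.75-fold higher and MSMO1 8.69-fold higher. The integrated stress response list had 6 members at least 2-fold higher and 3 lower among 26 and a median of 0.02 (percentile 38.4). Its higher members were HSPA5, HERPUD1, DDIT4, DDIT3, ASNS and CHAC1, and its lower members the amino acid transporter subunits SLC7A5 and SLC3A2 and the serine synthesis enzyme PSPH.

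The SASP list held 6 members at least 2-fold higher and 6 lower among 19 measured. The lower members were chemokines: CXCL2 (27.1-fold lower), CCL20 (50-fold lower, 13.5 to 419, from at least 102 and 2 reads), CXCL3 (6.13-fold), CXCL5 (4.15-fold, at 1668 and 402 FPKM) and CXCL8 (6.53-fold, at 37.9 and 5.8 FPKM), besides CXCL1. CXCL1, CXCL2 and CXCL3 are close paralogs among which reads can be split in counting. The higher members included CSF2, PLAU, the growth factors AREG (3.29-fold) and EREG (2.05-fold), and PLAUR. The median of 0.5 lay at percentile 99.2; with no filter it was 0.01 and with a mean of at least 5 FPKM it was 0.18, and in both cases the list was no longer beyond the random lists.

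Other lists with higher medians were EMT (0.75, percentile 99.5, 4 of 9 members at least 2-fold higher), STAT3 targets (0.51, percentile 98.2), colon epithelial markers (0.48, percentile 98.4), TGF-beta targets (0.45, percentile 97.7) and immediate early genes (0.43, percentile 98.9). The EMT call ended without the filter (median 0.3), and the STAT3, colon epithelial and TGF-beta calls ended at a mean of at least 5 FPKM (medians 0.57, 0.44 and 0.42). The higher EMT members were ITGA5 (3.17-fold), TGFBI (2.66-fold), MMP14 and LAMB3. Among colon epithelial markers, CEACAM5 was 4.87-fold higher and CLDN4 2.79-fold higher, CDX2, an intestinal transcription factor, was 2.78-fold lower, and EPCAM stood at 154 and 149 FPKM. Immediate early genes went both ways, with DUSP5 12.3-fold and PHLDA1 4.51-fold higher and EGR1 3.8-fold lower.

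The remaining lists lay within the random lists. Their medians were 0.26 for ribosomal proteins (percentile 93.9; 48 of 54 above 0), 0.23 for immune checkpoint and MHC genes (percentile 78.1), 0.18 for stemness (71.5), 0.16 for senescence and p53 (76.0), 0.11 for hypoxia and glycolysis (65.3), 0.09 for WNT targets (63.3), 0.05 for heat shock (47.4), 0.02 for tRNA modification and synthetases (40.1), 0.003 for abundant noncoding RNAs (37.4), -0.02 for interferon-stimulated genes (37.6) and -0.12 for translation factors (8.79). In the WNT and stemness lists LGR5 was 5.85-fold and ASCL2 6.86-fold lower, while SOX9 was 3.14-fold higher. Of 18 measured senescence and p53 genes, 5 were at least 2-fold higher, beside 1338 of all 14739 genes. They were BTG2, PLK3, GADD45B, BBC3 and CDKN1B. LMNB1 alone was at least 2-fold lower (2.52-fold). A list median does not show members that move both ways.

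Markers of other cell types were low in both libraries. Of 25 fibroblast markers 15 were in the table and 3 had a mean of at least 1 FPKM, with a median of -0.16 (percentile 35.7); S100A4 stood at 4.77 and 7.53 FPKM, FN1 at 3.12 and 1.71 FPKM, ACTA2 at 1.8 and 1.51 FPKM, VIM at 0.489 and 0.78 FPKM, PDGFRB at 0.0221 and 0.564 FPKM, COL6A1 at 0.0295 and 0.331 FPKM and COL1A1 at 0.0482 and 0.229 FPKM. Of the 15 markers, 11 were higher and 4 lower in S-CAFs-w13, 0 of them past 2-fold on the log2(FPKM + 1) scale. On that scale a gene under 1 FPKM in both libraries cannot reach 2-fold. All of the markers but S100A4, FN1 and ACTA2 were that low, so for them the count shows nothing. Without the filter the fibroblast list's median was 0.14 and lay above the random lists. The leukocyte and endothelial lists had 1 measured member each, CD14 at 1.17 and 1.54 FPKM and ESAM at 1.13 and 1.98 FPKM.

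The knockdown comparison asks what loss of METTL1 does to RNA levels. It rests on a single knockdown construct, sh2, so other effects of sh2 cannot be told apart from the loss of METTL1. METTL1 itself was 1.77-fold lower in knockdown input (1.37 to 2.29), at 5.8 FPKM in control and 3.28 FPKM in knockdown, from at least 159 and 100 reads. The authors' deposited table gave METTL1 a log2 fold change of -0.84. WDR4 stood at 13.03 and 15.6 FPKM, 1.20-fold higher in the knockdown (1.05 to 1.37). The NF-kB target list and the SASP list were lower beyond random lists. CXCL1 was 5.28-fold lower (4.33 to 6.47), at 42.7 and 8.1 FPKM, and LCN2, an iron-binding innate immune protein, was 4.16-fold lower (3.83 to 4.52), at 163 and 39.2 FPKM.

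Of 8400 genes with a mean of at least 1 FPKM, 36 were at least 2-fold higher and 47 at least 2-fold lower in the knockdown, with a median log2 ratio of 0.01. The counting interval excluded 2-fold for 19 higher and 30 lower genes. The other low genes of the 10 lowest were SAA1 (3.84-fold lower), CCL20 (6.47-fold), CXCL2 (3.39-fold), CXCL5 (3.07-fold), CENPV (4.87-fold), PI3 (3.05-fold), CXCL8 (3.72-fold) and PDZK1IP1 (3.01-fold). The 10 highest were C6orf15, PALM3, MSX1, CST7, PIGBOS1, C10orf95, MFSD6L, LGALS1, C17orf58 and GNB1L. CST7 stood at 16.4 and 44.5 FPKM, 2.72-fold higher (2.27 to 3.28), and the transcription factor MSX1 was 3.39-fold higher (2.58 to 4.52). C10orf95 stood at 0.195 and 1.99 FPKM, with an interval of 3.21 to 51.9.

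Of 22 lists with at least 3 measured members, 7 lay beyond the random lists, where 1.1 would by chance. The NF-kB list had 16 of 18 members below 0 and a median of -0.36 (percentile 0), with TNFAIP3 1.81-fold and BIRC3 2.07-fold lower besides LCN2 and SAA1. The SASP list had a median of -0.26 (percentile 0.01) with 5 of 12 members at least 2-fold lower, all of them chemokines; with no filter its median was -0.07 and no longer beyond the random lists. Ribosomal proteins (median -0.05, percentile 1.33) and tRNA modification and synthetases (-0.1, percentile 0.66) were lower by small amounts. Cholesterol synthesis genes (0.22, percentile 99.95, 15 of 16 above 0), colon epithelial markers (0.25, percentile 99.98) and WNT targets (0.14, percentile 98.0) were higher. INSIG1 was 1.58-fold and STARD4 1.75-fold higher. The WNT call ended at a mean of at least 5 FPKM, with a median of 0.1.

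The lists within the random lists had medians of 0.03 for m7G methyltransferases and cap genes (percentile 62.2), 0.04 for STAT3 targets (62.8), -0.11 for interferon-stimulated genes (7.86), -0.18 for EMT (5.09), 0.08 for TGF-beta targets (82.6), 0.05 for proliferation (83.5), 0.01 for senescence and p53 (57.0), 0.03 for hypoxia and glycolysis (62.2), -0.04 for the integrated stress response (17.1), 0.07 for immediate early genes (83.9), 0.05 for heat shock (75.1), -0.02 for translation factors (22.9), -0.07 for abundant noncoding RNAs (9.63), -0.05 for immune checkpoint and MHC genes (20.4) and 0.1 for stemness (82.1). Of the immediate early genes, FOS was 2.33-fold higher, at 3.13 and 7.31 FPKM, and no longer past 2-fold on the log2(FPKM + 1) scale when rescaled or on the authors' scaling. SNUPN, which imports capped small nuclear RNAs into the nucleus, was 2.1-fold lower in FPKM, a ratio not past 2-fold on that scale. Of the fibroblast markers, S100A4 alone was measured, at 5.79 and 11.2 FPKM. The leukocyte, endothelial and mitochondrial lists had 0 measured members in this table.

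**Figure D2:**
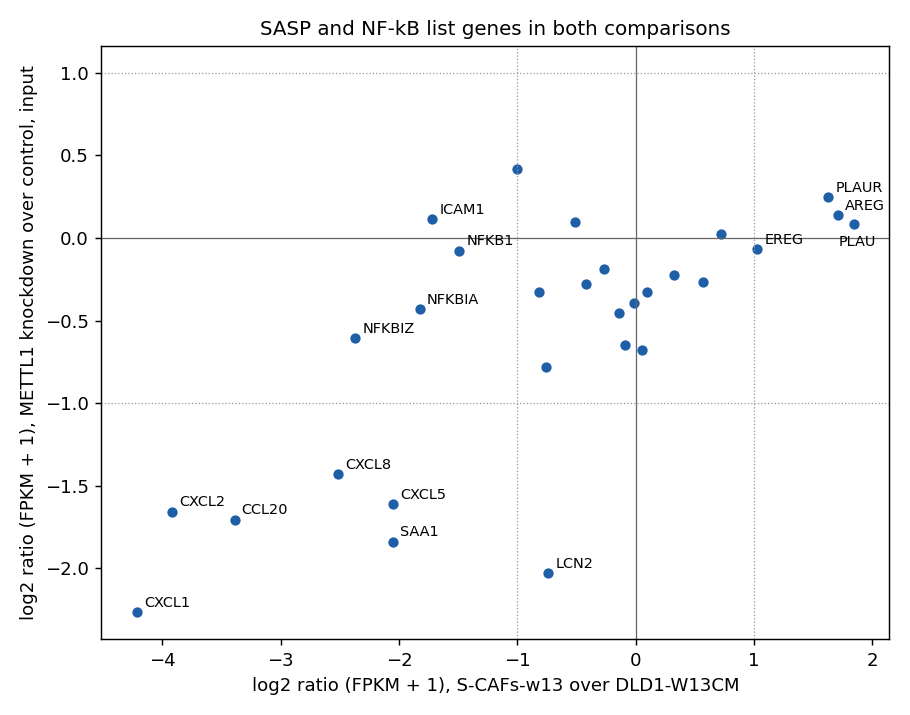
Log2 ratio of (FPKM + 1) in S-CAFs-w13 over DLD1-W13CM (x axis) and in METTL1 knockdown over control input (y axis) for the 29 members of the SASP and NF-kB lists measured in both tables. Points are genes, names mark those past 2-fold (dotted lines) in either comparison, and 17 genes lie below 0 in both.

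The m7G comparison asks which transcripts lose or gain m7G when METTL1 is reduced. The 5' UTR held more peaks than any other annotated location. Peaks were about evenly split between higher and lower m7G in the knockdown, read as knockdown over control, a direction the table does not state. Read as control over knockdown, every gain below would be a loss and every loss a gain, the share of lower peaks would be that of higher ones, and the m7G medians and Spearman's rho would change sign. Of 9450 peaks, 49.5% were annotated to the 5' UTR, 29.5% to the coding sequence, 18.6% to an exon and 2.06% to the 3' UTR, in the authors' deposited table. The median fold enrichment in the authors' deposited table was 14.9 for the 5' UTR, 9.93 for the coding sequence and 3.1 for the 3' UTR. The METTL1 transcript's own peak, in its 5' UTR (chromosome 12, 57772555 to 57772793), had a log2 change of -2.20 with an FDR of 0.635 in the authors' deposited table.

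**Figure D3:**
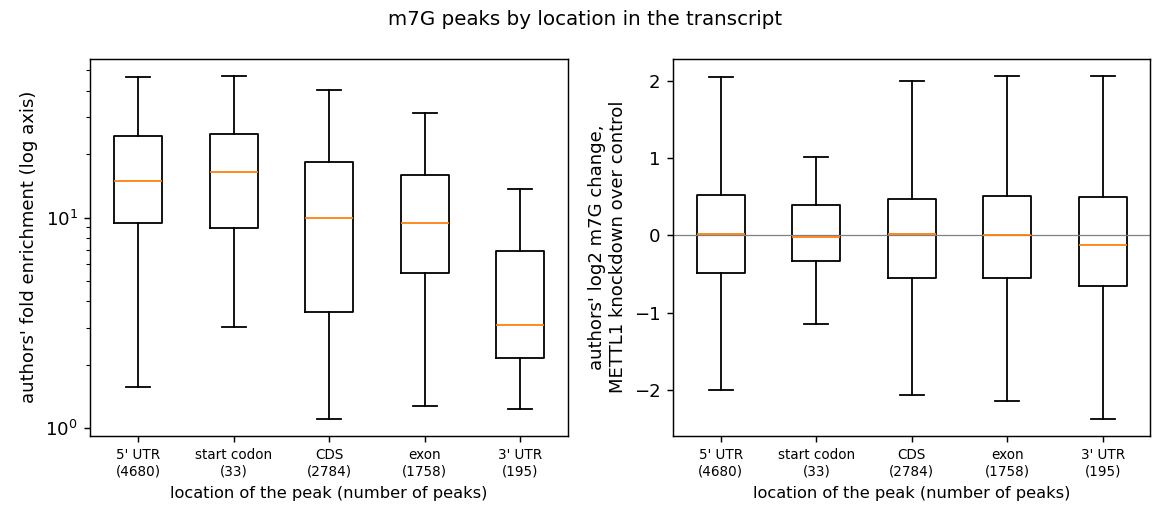
The authors' fold enrichment (left, log axis) and log2 m7G change, METTL1 knockdown over control as read here (right), of m7G peaks by annotated location (x axis, number of peaks in parentheses). Boxes span the quartiles with the median as a line, whiskers reach the last value within 1.5 times the quartile range and outliers are not drawn; median changes run from -0.13 in the 3' UTR to 0.02 in the 5' UTR.

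In all, 4597 of 9450 peaks had a lower m7G value in the knockdown, 48.6% (95% Clopper-Pearson interval 47.6 to 49.7, counting peaks only), and the median log2 change was 0.004. Read as control over knockdown, an alternative added after the data were seen, 50.1% were lower (49.1 to 51.1). With a single IP and a single input library of each line, the authors' p-values and FDRs cannot cover variation between cultures. At an FDR under 0.05 in the authors' deposited table, 290 peaks were higher and 206 lower; at a p-value under 0.05, 813 were higher and 709 lower. The largest losses at that FDR, under the reading as knockdown over control, were in RNF14 (5' UTR, chromosome 5, 141970719 to 141970868), TPMT, ZFC3H1, FEM1B, MT2A, RNF40, NAAA, MAGI3, NIPSNAP3A and ATP5C1. The peak of the metallothionein MT2A (exon, chromosome 16, 56608966 to 56609202) had a log2 change of -2.12 with an FDR of 7.9e-11 in the authors' deposited table. The peak of ZFC3H1 (coding sequence, chromosome 12, 71644206 to 71645003) had a log2 change of -2.44 with an FDR of 4.3e-05 in that deposited table of the authors.

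The largest gains under the same reading were in WRNIP1 (5' UTR, chromosome 6, 2766130 to 2766279), LRP11, HOOK2, the noncoding IGFL2-AS1, SNUPN, PRPF18, FLAD1, VPS28, CCDC9 and KIF1C. The peak of CCDC9 (coding sequence, chromosome 19, 47258339 to 47264649) had a log2 change of 1.95 with an FDR of 1.6e-11 in the authors' deposited table. The peak of SNUPN had a log2 change of 2.17 in that deposited table of the authors while its input was 2.1-fold lower. For MT2A, among the losses, input was 1.61-fold higher. How the authors' m7G change accounts for input is not given in the sources used here. The part of these changes that comes from input thus cannot be told. Coordinates are on the GRCh38 build. IGFL2-AS1 is an antisense RNA, and whether its reads were counted by strand is not given in the sources used here.

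Of 22 lists, 1 lay beyond the random lists, where 1.1 would by chance. Proliferation genes had lower m7G in 21 of 29 peaks (72.4%, against 48.6% of all peaks), with a median of -0.37 (percentile 0.2); at an FDR under 0.05, 5 of them were higher and 4 lower, CENPF with a log2 change of -1.13 in the authors' deposited table. Read as control over knockdown, the list had lower m7G in 8 of 29 peaks (27.6%) and a median of 0.37 (percentile 99.8), so its direction rests on the reading. Lower m7G was seen in 21.4% of SASP peaks (median 0.34, percentile 93.8), 33.3% of NF-kB peaks (0.22, percentile 85.2), 41.7% of peaks in m7G methyltransferases and cap genes (0.32, percentile 88.2), 31.6% in senescence and p53 genes (0.42, percentile 97.0), 37.5% in STAT3 targets (0.07, percentile 56.3), 44.4% in interferon-stimulated genes (0.13, percentile 67.9), 37.0% in tRNA modification and synthetases (0.12, percentile 71.0), 45.0% in immediate early genes (0.1, percentile 64.1) and 20% in EMT genes (0.17, percentile 65.7). It was seen in 57.1% of colon epithelial markers (median -0.07, percentile 27.6), 63.6% of TGF-beta targets (-0.33, percentile 7.5), 62.5% of WNT targets (-0.18, percentile 17.5), 66.7% of hypoxia and glycolysis genes (-0.19, percentile 17.0), 56.5% of the integrated stress response (-0.09, percentile 22.7), 68.8% of cholesterol synthesis genes (-0.15, percentile 20.7), 53.8% of heat shock genes (-0.08, percentile 25.7), 50% of ribosomal proteins (0.01, percentile 34.5), 57.9% of translation factors (-0.21, percentile 4.92), 50% of abundant noncoding RNAs (-0.01, percentile 38.1), 55.6% of immune checkpoint and MHC genes (-0.07, percentile 35.6) and 66.7% of stemness genes (-0.2, percentile 23.6). Read as control over knockdown, lower m7G was seen in 78.6% of SASP peaks, 66.7% of NF-kB peaks, 68.4% in senescence and p53 genes, 60% in EMT genes and 59.3% in tRNA modification and synthetases, and these lists lay within the random lists under that reading too. The fibroblast list had 1 peak, with a change of -0.09, and the leukocyte, endothelial and mitochondrial lists had 0.

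The overlap of m7G change with RNA change, read as knockdown over control, was counted at 2-fold in each; under the other reading higher and lower m7G change places. Of 8400 genes, 13 had higher m7G and lower input RNA, beside 4.97 from the list sizes, and 12 had lower m7G and higher input RNA, beside 4.01. Higher m7G with higher input RNA was seen in 2 genes, beside 3.81, and lower m7G with lower input RNA in 4 genes, beside 5.24. Across these genes, which are not independent replicates, Spearman's rho of the m7G and input changes was -0.15. Of 7945 genes also measured in the co-culture table, 70 had higher m7G and higher RNA in S-CAFs-w13, beside 48.8 from the list sizes, 45 higher m7G and lower RNA (beside 55.0), 52 lower m7G and higher RNA (beside 51.5) and 60 lower m7G and lower RNA (beside 58.0).

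Between the expression comparisons, an overlap chosen after the data were seen, 12 genes were at least 2-fold lower both in S-CAFs-w13 and in the knockdown, beside 2.38 from the list sizes. They included CXCL1, CXCL2, CXCL5, CXCL8, CCL20, SAA1, PI3 and PDZK1IP1, and ZC3H12A, an RNase that degrades inflammatory mRNAs, which stood at 18.4 and 5.1 FPKM in the co-culture and at 38.4 and 14.5 FPKM in the knockdown comparison. Of the other pairs of directions, 2 genes were higher in both (beside 1.39), 6 higher in the knockdown and lower in S-CAFs-w13 (beside 1.57) and 1 lower in the knockdown and higher in S-CAFs-w13 (beside 2.11).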

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

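The authors' scaling, the run without the mitochondrial genome, the counting interval, the overlap between the expression comparisons and the reading of the m7G change as control over knockdown were chosen after the data were seen. In the co-culture comparison the count of genes at least 2-fold higher was 639 at a mean of at least 5 FPKM, 731 for protein-coding genes and 653 by counting interval, and of lower genes 539, 636 and 500, and 1777 lower with a pseudocount of 0.1; fewer genes tested, or a stricter criterion, account for the smaller counts by construction. Without the filter, centred, rescaled or on the authors' scaling the counts stayed within 1.5 times the main ones. The number of lists beyond the random lists was 6 at a mean of at least 5 FPKM. In the knockdown input the higher and lower counts were 103 and 112 with a pseudocount of 0.1, 7 and 16 at a mean of at least 5 FPKM, 15 and 24 for protein-coding genes, and 19 and 30 by counting interval.

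The share of m7G peaks that were lower was 46.6% past a p of 0.05, 41.5% past an FDR of 0.05, 34.5% past an FDR of 0.005, 46.7% past an FDR of 0.05 and 4-fold, and 50% after centring, which is so by construction; for the others the cause was not tested. The counts of higher and lower peaks were 813 and 709 at a p of 0.05, 116 and 61 at an FDR of 0.005 and 8 and 7 with 4-fold as well. At a mean input of at least 5 FPKM, 2 lists lay beyond the random lists in m7G, proliferation and m7G methyltransferases and cap genes. Read as control over knockdown, the share of lower peaks was 50.1%, and it was 53.4% past a p of 0.05, 58.5% past an FDR of 0.05, 65.5% past an FDR of 0.005 and 53.3% with 4-fold as well. The proliferation list's median m7G change was then 0.37, the reverse of -0.37. Under that reading 12 genes had higher m7G and higher input RNA, 4 higher m7G and lower input RNA, 2 lower m7G and higher input RNA and 13 lower m7G and lower input RNA. All of these follow from the sign by construction. An IP over input ratio recomputed per line was not run, since IP values were not analysed here.

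At 1.5-fold in each, higher m7G was shared with 36 higher and 79 lower input genes and with 309 higher and 285 lower S-CAFs-w13 genes, and lower m7G with 73 higher and 44 lower input genes and with 291 higher and 325 lower S-CAFs-w13 genes. Higher input genes were shared with 47 higher (beside 26.5 from list sizes) and 27 lower S-CAFs-w13 genes (beside 29.1), and lower input genes with 27 higher (beside 29.8) and 55 lower ones (beside 32.7). More genes pass the lower fold by construction. No called list median changed sign under the pseudocount, the filters or centring. No named gene past 2-fold in expression changed sign under the pseudocount, centring, rescaling or the authors' scaling. This is so by construction, since a pseudocount keeps the sign and the other settings shift ratios by far less than 2-fold. Of the values of named genes under these alternatives, 588 of 624 in the co-culture and 405 of 408 in the knockdown input kept their side of 2-fold. Depth limits low genes most, as for CCL20, whose fold rests on at least 102 and 2 reads. No paired analysis was possible because each group holds 1 library.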

Other observations

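The genes in the next sentences were chosen after their values were seen, and the tests of explanations for the shared lower genes, the mitochondrial mRNAs and the m7G peaks near 5' ends were chosen after the results they bear on were known. Several homeobox genes of the HOXB cluster were higher in S-CAFs-w13: HOXB9 stood at 54.7 and 271 FPKM, 4.94-fold higher (4.6 to 5.32), HOXB4 was 5.27-fold higher (4.39 to 6.36), HOXB6 3.72-fold higher (3.18 to 4.36) and HOXB5 2.52-fold higher (2.14 to 2.97), while HOXB3 was 1.41-fold, HOXB7 1.42-fold and HOXB8 2.04-fold higher, HOXB13 stood at 1.5 and 1.35 FPKM, and HOXB2 at 1.15 and 0.551 FPKM. In the knockdown HOXB9 stood at 65.7 and 55.8 FPKM. The metallothioneins MT2A and MT1X, which bind zinc and copper, were 5.09-fold (4.52 to 5.75) and 7.82-fold higher (3.33 to 22.4) in S-CAFs-w13, with MT1E 1.52-fold higher; in the knockdown MT2A was 1.61-fold higher and MT1X 2.07-fold lower. Metallothionein genes are close paralogs among which reads can be split. The clock gene PER1 was 11.6-fold higher, the clock output factor DBP 8.14-fold higher and TXNIP, an inhibitor of thioredoxin, 7.49-fold higher in S-CAFs-w13; in the knockdown PER1 stood at 7.4 and 7.75 FPKM, DBP at 3 and 3.5 FPKM and TXNIP at 19.9 and 19.96 FPKM, with counting intervals that included no difference. LGALS1 was 10.6-fold higher in S-CAFs-w13 and 3.07-fold higher in the knockdown.

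Lists beyond the random lists in the same direction in both expression comparisons were NF-kB targets (medians -0.76 and -0.36), colon epithelial markers (0.48 and 0.25) and cholesterol synthesis (0.65 and 0.22). The colon epithelial call in S-CAFs-w13 ended at a mean of at least 5 FPKM. The SASP list was called in opposite directions, at 0.5 from 19 members in S-CAFs-w13 and -0.26 from 12 in the knockdown. Both SASP calls ended without the filter. Proliferation genes, lower in S-CAFs-w13 at a median of -1.21, had a median of 0.05 in the knockdown input. The difference between the comparisons was not tested.

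The 12 genes lower both in S-CAFs-w13 and in the METTL1 knockdown were 5.04 times as many as list sizes give. List sizes take genes as independent, which the chemokines among the 12 may not be, so the excess cannot decide against independent lists. Counting intervals lay below 1 in both comparisons for 9 of them. Choosing genes as 2-fold lower in both favours such intervals, so the 9 are no independent test of counting noise. For CXCL5 the intervals, 0.314 to 0.337 in the knockdown and 0.232 to 0.251 in the co-culture, argue against counting noise as the whole cause. Genes higher in the knockdown and lower in S-CAFs-w13 were in excess at 2-fold, 6 beside 1.57, but not at 1.5-fold, 27 beside 29.1. At 1.5-fold, genes lower in both were 55 beside 32.7 and genes higher in both 47 beside 26.5. Lower METTL1 as the cause of the co-culture difference as a whole is argued against by a Spearman's rho of 0.058 across genes (0.063 at a mean of at least 5 FPKM in both), though counting noise lowers rho and METTL1 was 1.77-fold lower in the knockdown and 2.71-fold lower in S-CAFs-w13, so a stronger loss was not examined. For these chemokines a link to METTL1 stays open as a hypothesis, as does a culture state shared by the libraries, which no value here tests.

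The mRNAs of the mitochondrial genome were lower in S-CAFs-w13 while both mitochondrial rRNAs had a mean log2 ratio of 0.025, close to the median of all genes, which argues against loss of all mitochondrial RNA from the library. Loss of cytoplasmic mRNA against nuclear RNA would raise MALAT1 and NEAT1, which were 5.13-fold and 11.9-fold higher, but ribosomal protein mRNAs had a median of 0.26, within the random lists, and 0 of 54 were at least 2-fold lower beside 11 of 13 mitochondrial mRNAs, which argues against it as the whole cause and leaves a part open. A difference in scaling is argued against by the median of all genes, 0.020. A difference in the processing or stability of mitochondrial mRNAs may be behind the pattern, as a hypothesis that was not tested, as may a difference in how far the libraries captured RNAs by their poly(A) tails.

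Peaks within 250 nt of the annotated 5' end of their gene were 68.8% of the 8402 peaks placed in a RefSeq gene, with a median enrichment of 15.4 against 5.4 for the other 2625 peaks, which is consistent with cap m7G being captured with internal m7G. The median change of peaks away from the 5' end lay -0.081 from that of peaks near it (95% resampling interval over peaks -0.139 to -0.0296), the direction that a fall of internal m7G hidden among cap peaks would give under the reading as knockdown over control, so that explanation stays open; under the other reading the sign turns. Whether a fall common to all peaks was removed when IP libraries were scaled to each other cannot be told apart from no fall, since the median change of 0.0043 follows from such scaling either way. Under the reading used, 79 genes at 1.5-fold had higher m7G and lower input RNA, beside 49.0 from list sizes. This excess may reflect that a gene's input counting error enters both measures with opposite sign. Under the other reading the same 79 genes would have lower m7G and lower input RNA, an excess that such an error would not give. Genes with higher m7G and lower input RNA would then be 44 beside 51.2.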
